A study of Mus musculus with 6 samples.

How the data were processed

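The analysis started from 1 table of the series with 3961 genes and 6 columns of values, 1 per library. From the values, the authors deposited log2 abundances with 1 added before the logarithm: with 1 taken off again (an offset of 1), all 3961 genes differ by at least 2-fold between the means of some pair of groups, against 2068 genes with an offset of 0 and 2187 with an offset of 2. The same count shows that the genes were preselected on a difference of that size, so counts of calls describe this set and not all genes. Whether the abundance was FPKM or TPM, and what test or other filter the authors used, is not given in the sources used here. The submitters' processing notes name Trimmomatic 0.38, HISAT2 2.1.0, Bowtie2, SAMtools 1.9, StringTie 2.1.3b and the genome build mm10. Per the labels, the libraries were prepared from total RNA by a capture kit that selects target sequences (Agilent SureSelect RNA Direct).

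The groups, tests, gene lists and most processing alternatives were fixed before the data were examined. That design assumed a table of all genes. As the values were already logged and preselected, no filter was applied, so the alternative without a filter equals the fit used, and an adjustment over the 49997 gene symbols of the RefSeq annotation (GRCm38.p6) was added after the data were seen. Of the 3961 symbols, 3855 (97.3%) occur in that annotation, which gave the gene positions, 4 are date-like and 1009 genes had an abundance under 1 in all libraries.

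The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 3 groups, all 6 libraries, a trended prior variance, 3 residual degrees of freedom and a median prior of 3.61. Adjusted p-values are those of Benjamini and Hochberg over the 3961 genes, and a gene was said to rise or fall where its adjusted p was under 0.05. The list tests were camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, for the 17 of 26 lists with at least 5 measured genes. Camera compares a list with the other genes. Fry asks only whether a list changed in a direction, and preselection of changed genes favours its calls. With an estimated correlation camera rests on the 3 residual degrees of freedom. A call lost there may reflect these as well as correlation, which for LXR targets was estimated at -0.072. Many lists then share 1 adjusted p, though unadjusted camera values with infection differed, as 0.0437 for stress-response and 0.322 for interferon-stimulated genes. Some named genes had the largest fold changes among genes with an adjusted p under 0.05. Their group values did not overlap, and their mean log2 value was above 1.97 in a group. Others had the largest moderated t in a list or were fixed in advance. Lack of overlap alone occurs by chance in a given direction in 16.7% of unselected genes with 2 libraries per group. Of these 3961 genes it held for 3412 with infection, 2999 with V46 in infected cells and 3733 with V46 against uninfected cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Data were also simulated with independent noise for each gene at the fitted variances. For V46 against infected cells, limma recovered 44.8% of changes of 0.5 log2 units, 94.0% of those of 1 and 100% of those of 2. There were 6 false calls among 165. In the real libraries genes of a list move together, so this does not measure false calls in the real data.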

Results

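RNA was sequenced from mouse bone marrow-derived macrophages, primary macrophages grown from marrow precursors, in 3 groups of 2 libraries each. The groups were uninfected cells, cells infected with Mycobacteroides abscessus, a rapidly growing mycobacterium, and infected cells treated with V46. The series presents V46, known here only by this code name, as a compound that acts on autophagy and on transcription factor EB, a regulator of lysosomal genes. The dose of bacteria, the dose of V46 and the sampling times are not given in the sources used here. Each library was represented by the log2 abundance of 3961 genes, with 1 added to each abundance before the logarithm, so that fold changes of low genes are understated. The table held only genes whose mean abundance, with the added 1 taken off, differed by at least 2-fold between some pair of groups, and the read depth of the libraries was unknown.

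The replicates resembled each other closely. Across genes, which are not independent replicates, the Pearson correlation between the 2 libraries of a group was 0.992 for uninfected cells, 0.993 for infected cells and 0.998 for V46-treated cells. More than 1 log2 unit separated the 2 libraries in 53 genes of uninfected cells, 67 genes of infected cells and 5 genes of V46-treated cells. In a principal component analysis the first component held 79.6% of the variance and separated uninfected from infected libraries, and the second held 16.4% and separated infected libraries with and without V46. Preselection of genes that differ between group means favours such a separation, so it is no test of a difference between groups. The labels do not say whether replicates came from separate cultures or animals, so all p-values measure the spread between these libraries only, which may be technical.

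The first comparison asked what infection did to the macrophages. Cxcl3, a neutrophil-attracting chemokine (chromosome 5, 90786101 to 90788093), rose by 6.18 log2 units (SE 0.23, n = 2 per group, limma adjusted p = 1.39e-05). Il1b, which encodes the cytokine interleukin-1 beta (chromosome 2, 129364569 to 129371164), rose from log2 abundances of 1.47 and 3.54 in the uninfected libraries to 8.56 and 8.58 in the infected ones (log2 fold change 6.06, SE 0.57, limma adjusted p = 0.000129). The other genes with the largest increases were Cxcl2 (6.11 ± 0.64), Gbp5 (6.07 ± 0.54), Cxcl1 (5.79 ± 0.61), Cfb (5.72 ± 0.59), Il1a (5.70 ± 0.22), Saa3 (5.70 ± 0.62), Fpr2 (5.46 ± 0.67) and Tarm1 (5.36 ± 0.32), given as log2 fold change ± SE. Among the genes that fell, Hpgd, which encodes the enzyme that inactivates prostaglandins (chromosome 8, 56294552 to 56321046), changed most (log2 fold change -4.86, SE 0.14, limma adjusted p = 9.29e-06), followed by the transporter gene Slco2b1 (-4.32 ± 0.25), Rnf150 (-3.86 ± 0.15), Tmem37 (-3.79 ± 0.15), Zdhhc14 (-3.54 ± 0.13), Slc46a3 (-3.51 ± 0.15), Rasgrp3 (-3.46 ± 0.20), Trav13-4-dv7 (-3.30 ± 0.16), Slc36a2 (-3.29 ± 0.14) and Abcd2 (-3.12 ± 0.11).

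Of the 23 measured genes for proinflammatory cytokines and feedback regulators of the transcription factor NF-kB, 23 rose with infection, and 23 also when adjusted over the list alone. Besides Il1b and Il1a they included Il6 (log2 fold change 5.10, SE 0.14, limma adjusted p = 9.29e-06), Tnf (log2 fold change 4.63, SE 0.27, limma adjusted p = 2.51e-05) and Il12a (4.27). The list as a whole moved up relative to the other genes (camera, adjusted p = 1.97e-10), a call that was lost with adjusted p = 0.429 with an estimated correlation. Genes of this kind were not equal in the uninfected libraries: of 43 abundant genes at least 16-fold higher in infected cells than in uninfected replicate 2, 42 were higher in uninfected replicate 2 than in replicate 1, with a median difference of 0.63 log2 units. Of 16 chemokine genes, 14 rose and 1 fell, with the same counts adjusted over the list alone. Ccl4, Ccl3 and Ccl22 changed by 4.51, 4.25 and 2.46, while Cxcl14 fell (-1.19) and Cxcl9 did not pass (-0.20, SE 0.67). The chemokine list moved up (camera, adjusted p = 5.11e-05, and adjusted p = 0.429 with an estimated correlation). Of 15 genes listed as negative feedback regulators of inflammation, 15 rose, and 15 adjusted over the list alone. Among them were Socs3 (4.17), Il1rn (3.61), Il10 (1.68) and Ptges (3.84), the gene of a prostaglandin E synthase that also serves inflammation. The list moved up (camera, adjusted p = 2.89e-07, and adjusted p = 0.429 with an estimated correlation).

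Interferon-stimulated genes also rose, 32 of 33 measured and 32 adjusted over the list alone, with a median log2 fold change of 1.87. Examples were Ifit1 (3.89 ± 0.39), Ifi205 (3.68 ± 0.25), Isg15 (3.61 ± 0.30) and Rsad2 (3.09 ± 0.35), and the list moved up relative to other genes (camera, adjusted p = 9.19e-08, and adjusted p = 0.429 with an estimated correlation). The 2 infected libraries differed in this list, with a median log2 value higher by 1.06 in replicate 1 and 33 of 33 genes higher there. Of 19 antimicrobial effector genes, 18 rose, and 18 adjusted over the list alone. They included the guanylate-binding protein genes Gbp5, Gbp7 (3.82) and Gbp3 (4.15), the scavenger receptor gene Marco (5.23), the itaconate-producing enzyme gene Acod1 (4.88) and Nos2, the gene of inducible nitric oxide synthase (log2 fold change 2.85, SE 0.44, limma adjusted p = 0.00113), and the list moved up (camera, adjusted p = 4.23e-06, and adjusted p = 0.429 with an estimated correlation).

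Stress-response genes rose together with infection. Of 17 genes of the integrated stress response and the unfolded protein response, 17 rose, and 17 adjusted over the list alone, such as Phgdh (3.04), Ppp1r15a (1.87), Slc7a5 (1.83) and Mthfd2 (1.47). Of 11 targets of NRF2, the transcription factor of the oxidative stress response, 11 rose, and 11 adjusted over the list alone, with the cystine transporter gene Slc7a11 (4.06) in the lead and with Srxn1 (1.96) and Txnrd1 (1.68). The lists moved up (camera, adjusted p = 9.19e-08 and 1.03e-05), and each had adjusted p = 0.429 with an estimated correlation. In the list of cell death and inflammasome genes, 7 of 10 rose and 2 fell, and the counts adjusted over the list alone were equal. Nlrp3 (2.91), Casp4 (2.40) and Bcl2a1d (2.16) rose, and the list moved up (camera, adjusted p = 0.0129, and adjusted p = 0.429 with an estimated correlation), though not with an abundance of at least 5 in 2 libraries (adjusted p = 0.0896). In the list of glycolysis and hypoxia genes, 4 of 6 rose and 2 fell, also adjusted over the list alone, and the list was not called (camera, adjusted p = 0.153). The glucose transporter gene Slc2a1 (1.29) and the lactate transporter gene Slc16a3 (1.28) were among those that rose, and Car9 (-0.68) fell.

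Lipid genes moved in both directions. Of 20 genes of cholesterol synthesis and uptake, 16 rose and 2 fell, and the same numbers did so adjusted over the list alone. The rises were small, as in Mvd (1.25 ± 0.10), Fdft1 (0.69 ± 0.088) and Sqle (0.65 ± 0.10), and Dhcr7 fell (-1.03). Without uninfected replicate 2, infected replicate 2 or either V46 library, the number that fell was 1, and with the adjustment over 49997 symbols 10 rose and 1 fell. The list was called up (camera, adjusted p = 0.000612, and adjusted p = 0.429 with an estimated correlation), and after quantile normalization it was not (camera, adjusted p = 0.0911). Among 10 targets of the sterol sensor LXR and lipid-handling genes, 7 fell and 1 rose, also adjusted over the list alone. The nuclear receptor gene Pparg (-1.86 ± 0.11), the cholesterol exporter gene Abcg1 (-1.39 ± 0.14) and the lipid droplet gene Plin2 (-1.04 ± 0.1) fell (camera, adjusted p = 0.0271, and adjusted p = 0.429 with an estimated correlation). Of 7 genes of alternative activation and scavenging, 6 fell and 1 rose, also adjusted over the list alone, including Mertk (-2.54), a receptor for apoptotic cells, and Arg1 (-1.26). This last list was near the threshold (camera, adjusted p = 0.0485, and adjusted p = 0.429 with an estimated correlation), and without infected replicate 1 it was not called (adjusted p = 0.0685), nor without V46 replicate 1 (0.0569) or V46 replicate 2 (0.0566). Other settings ended this call too, namely a pseudocount of 0.1 (0.0508) or 5 (0.0515), an abundance of at least 5 (0.0536) or 1 (0.0672) in 2 libraries and a fit of only the 2 groups compared (0.0559).

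Few genes of the lysosome and of autophagy were analysed here. Each was preselected for a difference of at least 2-fold between some pair of groups. Counts such as 3 of 3 therefore do not describe the other genes of these lists. Those genes were absent, for lack of such a difference or for another reason. Sqstm1, which encodes an autophagy receptor, rose with infection (log2 fold change 1.49, SE 0.12, limma adjusted p = 6.93e-05), as did Optn (0.86) and Gabarapl1 (0.56), so that 3 of 3 measured autophagy genes rose, of 36 in the list, and 3 adjusted over the list alone. Of 3 measured lysosomal genes, of 40 in the list, 2 rose, among them Clcn7 (1.34), and Sgsh, the gene of a heparan sulfate hydrolase, fell (-2.92). The proton pump subunit genes Atp6v1e1 (0.89) and Atp6v1h (0.84) rose. Rragd, the gene of a GTPase that carries nutrient signals at the lysosome, fell (log2 fold change -0.997, SE 0.14, limma adjusted p = 0.000732). After quantile normalization 3 of these calls ended, with limma adjusted p = 0.0732 for Atp6v1e1, 0.0875 for Atp6v1h and 0.243 for Gabarapl1. Tfeb, Tfe3, Lamp1 and Map1lc3b were not analysed here, and neither were the listed genes of oxidative phosphorylation and ribosomal proteins.

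Markers of macrophage identity and of other marrow cells moved as well. Of 7 macrophage identity genes, 4 fell and 2 rose, also adjusted over the list alone, with Fcgr1 (-1.91) and Fcgr3 (-1.11) falling and Cd14 (1.42) and Msr1 (1.06) rising (camera, adjusted p = 0.356). Of 8 neutrophil markers, 7 fell and 1 rose, also adjusted over the list alone. Mpo (-2.75) and Elane (-2.01), granule genes of immature neutrophils, fell, and the gelatinase gene Mmp9 (2.28) rose (camera, adjusted p = 0.036, and adjusted p = 0.429 with an estimated correlation). Without uninfected replicate 2, or with an abundance of at least 5 in 2 libraries, this list was not called (adjusted p = 0.0536 in each case). Of 5 dendritic cell markers, 3 rose and 1 fell, of 7 lymphocyte markers 3 fell, and of 7 stromal, mast cell and erythroid markers 1 rose, with equal counts adjusted over the list alone and no list call (camera, adjusted p = 0.394, 0.26 and 0.962). Without infected replicate 2 the lymphocyte list had 6 genes that fell, without uninfected replicate 2 or infected replicate 1 it had 2, and without infected replicate 1 the stromal list had 3 that fell. The median of the stromal list was -0.19 and its mean 0.04, and camera gave an upward direction. The small lists gave Cdkn1a (1.41) and Mki67 (1.56) among 3 of 4 cell cycle genes that rose, Mt2 (2.02) among 2 of 3 heat shock and metallothionein genes that rose, and H2-Oa (0.52) as the 1 of 3 genes of antigen presentation that rose, a call not made when adjusted over the list alone or without uninfected replicate 1, infected replicate 2 or either V46 library.

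In all, 1268 of 3961 genes were higher and 1584 lower in infected than in uninfected cells, and 1109 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05). With the adjustment extended to 49997 RefSeq gene symbols, since the table held only preselected genes, 968 were higher and 996 lower. Under it, counts moved by over 1.5 times in the lists of cholesterol genes, LXR targets (0 rose), glycolysis (0 fell), dendritic cell markers (1 rose), heat shock (0 fell) and antigen presentation genes (0 rose). After median centring, which moved the median change of all genes from -0.15 to -0.03, there were 1393 and 1234. By fry, 16 of the 17 tested lists were called, all but the stromal, mast cell and erythroid markers (adjusted p = 0.896), including the lists that camera did not call, namely glycolysis (0.00172), macrophage identity (0.000536), dendritic cell (0.0232) and lymphocyte genes (0.0202). As fry makes no comparison with other genes and most of these preselected genes passed, its calls do not set a list apart.

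**Figure D1:**
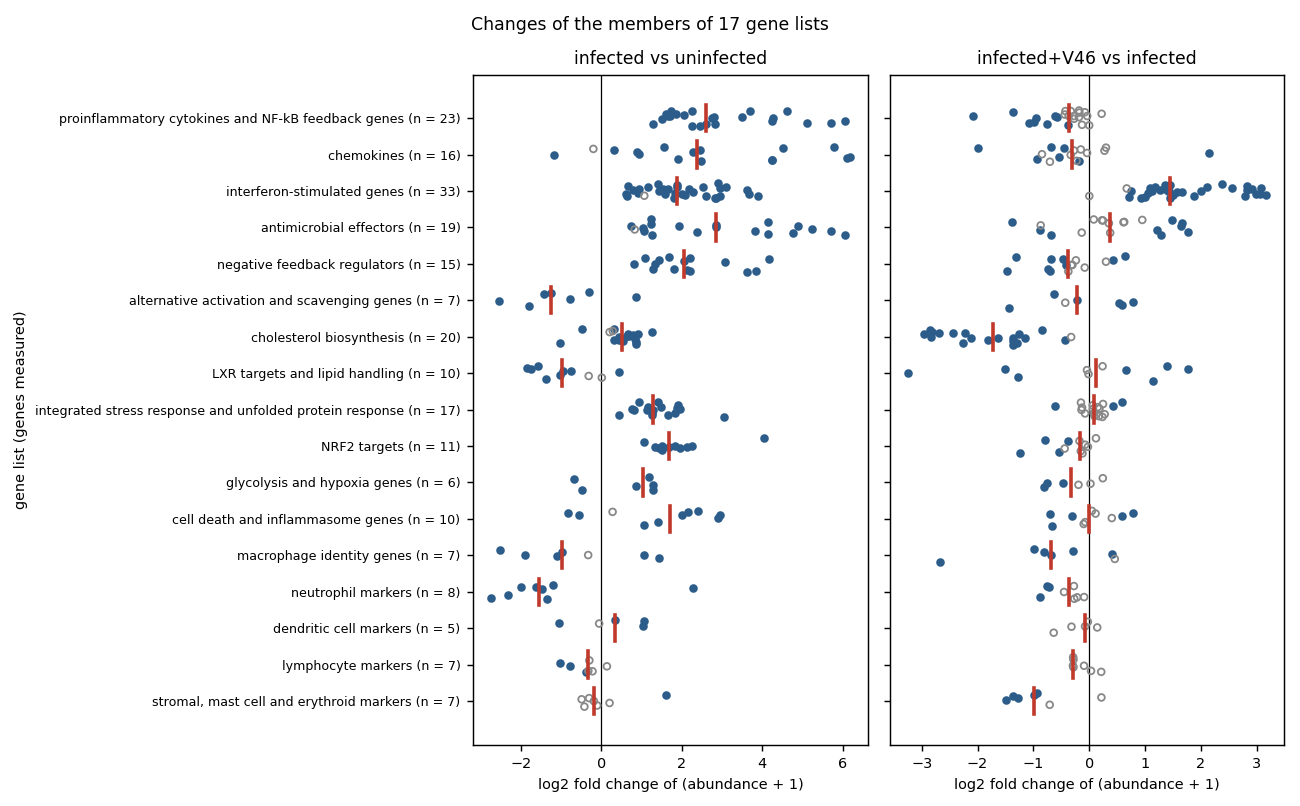
Log2 fold changes of the measured members of 17 gene lists, with infection (left) and with V46 in infected cells (right). Each point is a gene, filled where the limma adjusted p was under 0.05 and open otherwise, and the red bar is the median, which for interferon-stimulated genes is at 1.87 with infection and 1.45 with V46, and cholesterol genes 0.51 and -1.73.

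The comparison of infected cells with and without V46 asked what the compound changed. Rsad2, which encodes the antiviral enzyme viperin (chromosome 12, 26442743 to 26456452), rose by 3.17 log2 units with V46 (SE 0.35, n = 2 per group, limma adjusted p = 0.00109). The other genes with the largest increases were Cmpk2 (3.07 ± 0.39), Ifit2 (3.05 ± 0.42), Trim30c (2.99 ± 0.38), Ifit3b (2.98 ± 0.36), Ifit3 (2.92 ± 0.48), Usp18 (2.82 ± 0.35), Mx2 (2.82 ± 0.36), Ifit1 (2.80 ± 0.39) and Mx1 (2.55 ± 0.38). Scd2, which encodes a fatty acid desaturase (chromosome 19, 44293676 to 44306864), fell most (log2 fold change -3.25, SE 0.10, limma adjusted p = 2.75e-05). Other large decreases were Tmc3 (-3.07 ± 0.21), Idi1 (-2.85 ± 0.11), Sqle (-2.84 ± 0.10), Cyp51 (-2.70 ± 0.086), Cx3cr1 (-2.68 ± 0.16), Stard4 (-2.43 ± 0.11) and Fads2 (-2.43 ± 0.17).

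**Figure D2:**
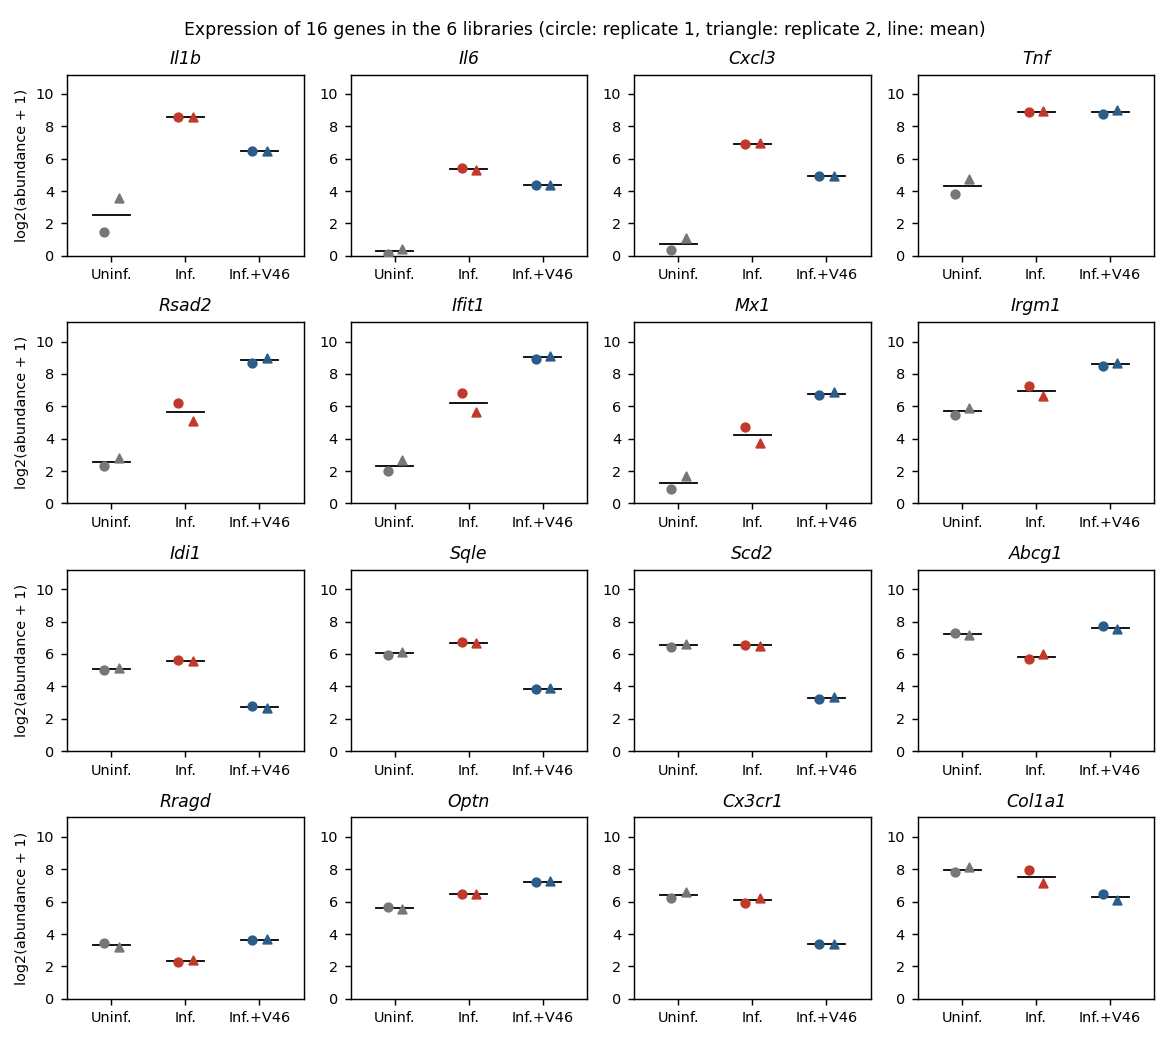
Log2(abundance + 1) of 16 genes in the 6 libraries, with a circle for replicate 1, a triangle for replicate 2 and a line for the mean of each group. Il1b lies at 8.56 and 8.58 in the infected libraries and at 6.47 and 6.49 with V46, whereas Tnf lies between 8.79 and 9.04 in all 4 infected libraries.

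Of 33 measured interferon-stimulated genes, 31 rose with V46, and 32 did so adjusted over the list alone, with a median log2 fold change of 1.45. Ifi205 did not pass (-0.0011, SE 0.25). Transcription factors of the interferon response were among those that rose, namely Irf7 (1.87), Irf9 (0.71) and Stat2 (1.08). The list moved up relative to other genes (camera, adjusted p = 7.56e-13), a call that was lost with adjusted p = 0.768 with an estimated correlation, and fry did not call it (adjusted p = 0.124). Infected replicate 1 lay above infected replicate 2 in this list by a median of 1.06, and the median change with V46 was 1.04 against replicate 1 alone and 2.03 against replicate 2 alone. Without V46 replicate 1 the number of genes that rose was 18, and without V46 replicate 2 it was 13, with medians of 1.56 and 1.38. With the adjustment over 49997 RefSeq symbols it was 10, and Ifit3 did not pass (limma adjusted p = 0.0562). Reads of close paralogs such as Ifit3 and Ifit3b or Oas1a and Oas1g may have been divided between genes, so single values there are uncertain, and the RefSeq annotation lists Mx1 and Mx2 as transcribed pseudogenes.

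Of 20 genes of cholesterol synthesis and uptake, 19 fell with V46, and 20 did so adjusted over the list alone. The median log2 fold change was -1.73, and the list moved down (camera, adjusted p = 1.59e-13, and adjusted p = 0.768 with an estimated correlation), as it did by fry (adjusted p = 0.000652). Sqle, the gene of squalene epoxidase (chromosome 15, 59315092 to 59331193), fell (log2 fold change -2.84, SE 0.10, limma adjusted p = 4.22e-05), as did Fdft1 (-2.11 ± 0.088) and Srebf2 (-1.37 ± 0.086), the gene of the transcription factor that controls the pathway. Dhcr7 did not pass over all genes (log2 fold change -0.33, SE 0.12, limma adjusted p = 0.0661). Without any single library 17 to 19 genes of the list fell, and with the adjustment over 49997 symbols 17 did. In the list of LXR targets and lipid handling, 4 of 10 genes rose and 3 fell, also adjusted over the list alone. The genes that rose were the sterol exporter gene Abcg1 (log2 fold change 1.77, SE 0.14, limma adjusted p = 0.000544), Pparg (log2 fold change 1.39, SE 0.11, limma adjusted p = 0.000489), the fatty acid carrier gene Fabp4 (1.14) and Plin2 (0.65), and those that fell were the lipogenic genes Scd2, Fasn (-1.28) and Scd1 (-1.51). Adjusted over 49997 symbols, 4 rose and 2 fell. The median of this list was 0.11 and its mean -0.09, camera gave an upward and fry a downward direction, and neither passed (camera, adjusted p = 0.429, and fry, adjusted p = 0.169).

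Part of the inflammatory genes fell with V46. Of 23 genes for proinflammatory cytokines and NF-kB feedback, 9 fell and 0 rose, also adjusted over the list alone, and 14 did not pass. Il6 (chromosome 5, 30013114 to 30019975) fell (log2 fold change -0.98, SE 0.14, limma adjusted p = 0.00289), as did Lif (-1.36 ± 0.16) and Il12a (-1.09 ± 0.18). Il1b was lower in both V46 libraries (log2 fold change -2.09, SE 0.57, limma adjusted p = 0.0293). That SE rested on the uninfected libraries, which differed by 2.07 log2 units in this gene and are not part of the comparison. The change was -2.07 without V46 replicate 1 and -2.10 without V46 replicate 2. It was -2.09 without infected replicate 1 and -2.08 without infected replicate 2. Il1b did not pass in these fits, which kept both uninfected libraries, nor with a pseudocount of 0.1 (limma adjusted p = 0.0502). Tnf did not pass (log2 fold change -0.0024, SE 0.27, limma adjusted p = 0.995). The list moved down (camera, adjusted p = 0.0394, and adjusted p = 0.768 with an estimated correlation). Fry did not call it (adjusted p = 0.169), and camera did not call it without infected replicate 2 (adjusted p = 0.141) or without V46 replicate 1 (adjusted p = 0.168). It was not called either with a pseudocount of 0.1 (0.106) or an abundance of at least 5 (0.104) or 1 (0.0775) in 2 libraries. The number of its genes that fell was 4 without infected replicate 1 or 2 and 3 without V46 replicate 1 or 2. Adjusted over 49997 symbols it was 2, and Il12a and Il1b did not pass (limma adjusted p = 0.0549 and 0.37).

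Of 16 chemokine genes, 6 fell and 1 rose with V46, also adjusted over the list alone. Cxcl3 fell (log2 fold change -1.99, SE 0.23, limma adjusted p = 0.0013) and so did Cxcl5 (-0.93), while Cxcl10, an interferon-inducible chemokine gene (chromosome 5, 92346638 to 92348889), rose (log2 fold change 2.14, SE 0.37, limma adjusted p = 0.00515). The list was not called (camera, adjusted p = 0.256), and the number that fell was 2 without infected replicate 1 or V46 replicate 2, 3 without V46 replicate 1 and 4 without infected replicate 2. Adjusted over 49997 symbols, 1 fell and 0 rose, and Cxcl10 and Cxcl5 did not pass (limma adjusted p = 0.065 and 0.0653). Of 15 negative feedback regulators, 7 fell and 2 rose, or 8 and 3 adjusted over the list alone. Socs3 (-1.48 ± 0.24) and Cish (-1.31 ± 0.21), genes of cytokine signalling inhibitors, fell, and Il10 did not pass (log2 fold change -0.38, SE 0.12, limma adjusted p = 0.0507). That list was not called (camera, adjusted p = 0.187), and 2 genes fell without V46 replicate 1 and 4 without V46 replicate 2, while 1 rose without infected replicate 1 or V46 replicate 1 and 0 without V46 replicate 2. Under that wider adjustment 1 fell and 0 rose, and Socs3 did not pass (limma adjusted p = 0.0526). Il10 passed without infected replicate 2 (limma adjusted p = 0.0438), with a pseudocount of 5 (0.0229), with no trend (0.0293) and with an abundance of at least 1 (0.0382).

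Antimicrobial effector genes went in both directions, with 6 of 19 rising and 3 falling, also adjusted over the list alone (camera, adjusted p = 0.187). The genes that rose were those of interferon-inducible GTPases, Irgm1 (1.64 ± 0.23), Irgm2 (1.76 ± 0.30), Igtp (1.47 ± 0.30), Tgtp1 (1.67 ± 0.46), Gbp7 (1.27 ± 0.28) and Gbp3 (1.21 ± 0.34). Those that fell were Marco (-1.38 ± 0.41), Slpi (-0.89 ± 0.20) and Lcn2 (-0.68 ± 0.14). Nos2 did not pass (log2 fold change 0.37, SE 0.44, limma adjusted p = 0.523), nor did Acod1 (0.23). Without V46 replicate 1 the list had 2 genes that rose and 0 that fell, without V46 replicate 2 it had 2 and 1, without infected replicate 1 it had 5 and 1, and without infected replicate 2 it had 4 and 2. Igtp did not pass without V46 replicate 1 or 2 (limma adjusted p = 0.0564 and 0.0722), nor Lcn2 without V46 replicate 1 (0.0625). The adjustment over 49997 symbols left 1 gene of the list that rose and 0 that fell, and of the genes named here only Irgm1 passed, with limma adjusted p = 0.0596 for Irgm2, 0.125 for Igtp and 0.132 for Lcn2.

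The autophagy genes Optn (0.75 ± 0.092) and Gabarapl1 (0.56 ± 0.092) rose with V46, 2 of the 3 preselected ones and 2 adjusted over the list alone. Sqstm1 did not pass (log2 fold change 0.14, SE 0.12, limma adjusted p = 0.374). These counts, too, do not describe the absent genes of the lists. Rragd (chromosome 4, 32982998 to 33022180) rose (log2 fold change 1.31, SE 0.14, limma adjusted p = 0.000981), opposite to its change with infection. Of 3 lysosomal genes Sgsh rose (log2 fold change 0.59, SE 0.11, limma adjusted p = 0.00818), and 2 did so adjusted over the list alone, with Clcn7 (0.29) not passing over all genes. Of 2 proton pump genes Atp6v1h rose (log2 fold change 0.56, SE 0.097, limma adjusted p = 0.00535), and 2 did so adjusted over the list alone. Without V46 replicate 1 Sgsh did not pass (limma adjusted p = 0.0667), and without V46 replicate 2 Atp6v1h did not (limma adjusted p = 0.051). Of these genes, with 49997 symbols in the adjustment, Optn and Rragd passed and Gabarapl1 (0.0546), Sgsh (0.103) and Atp6v1h (0.0676) did not, so that 1 autophagy, 0 lysosomal and 0 proton pump genes rose. Clcn7 passed after median centring (0.47, limma adjusted p = 0.0341), as did Atp6v1e1 (0.43, 0.0387).

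The remaining lists were not called by camera with V46, and of those in this paragraph fry called the glycolysis and hypoxia genes down (adjusted p = 0.0276). Of 17 stress-response genes, 14 did not pass, 2 rose and 1 fell, and adjusted over the list alone 1 rose and 0 fell (camera, adjusted p = 0.187). Without either V46 library 0 of them passed, 1 NRF2 target and 2 glycolysis genes fell and 0 cell death genes rose, and without infected replicate 2 these last numbers were 2, 2 and 0. The number of cell death genes that fell was 1 without V46 replicate 1. Of 11 NRF2 targets 4 fell, led by Me1 (-1.23), of 6 glycolysis and hypoxia genes 3 fell, led by Pfkfb4 (-0.80) and Adm (-0.75), and of 10 cell death genes 3 fell, among them Bcl2l11 (-0.66), and 2 rose, with equal counts adjusted over the list alone (camera, adjusted p = 0.187, 0.254 and 0.946). Of 7 genes of alternative activation 3 rose and 3 fell, or 3 and 4 adjusted over the list alone, with Gas6 (0.79) and Arg1 (-1.44) as examples (camera, adjusted p = 0.98). Its median was -0.23 and fry gave a downward direction, while camera gave an upward one, and without V46 replicate 2 the number that rose was 1. The cell death list had a median of -0.01, a mean of 0.0054 and the same disagreement of directions. Of 3 genes of antigen presentation Ifi30 rose (1.01) and Cd80 fell (-1.06), also adjusted over the list alone. In the cell cycle list Ccnb1 rose (0.72) and Mki67 fell (-0.59), and among heat shock and metallothionein genes the zinc transporter gene Slc30a1 rose (0.93), each also adjusted over the list alone. Ccnb1 did not pass without V46 replicate 1 or 2 (limma adjusted p = 0.0657 and 0.058), nor Mki67 without V46 replicate 1 (0.0623) or after median centring (0.0571). Over 49997 symbols, 0 genes passed in the stress-response, cell death and cell cycle lists, 1 NRF2 target and 2 glycolysis genes fell, and 1 gene of alternative activation rose and 1 fell. Bcl2l11, Ccnb1 and Mki67 were among those that did not pass (0.0533, 0.11 and 0.098).

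Among macrophage identity genes 5 of 7 fell and 1 rose with V46, also adjusted over the list alone (camera, adjusted p = 0.187, and fry, downward, adjusted p = 0.000652). Without either V46 library 0 of them rose. Cx3cr1, the fractalkine receptor gene (chromosome 9, 120048683 to 120068296), fell (log2 fold change -2.68, SE 0.16, limma adjusted p = 0.00026), and so did Maf (-0.99 ± 0.11) and Msr1 (-0.30 ± 0.087). Of 7 stromal, mast cell and erythroid markers 5 fell, among them the collagen genes Col1a1 (-1.28 ± 0.27) and Col3a1 (-1.36 ± 0.33), while adjusted over the list alone 5 fell and 1 rose (camera, adjusted p = 0.187). The mean log2 value of 3 collagen genes was 7.43 and 7.89 in the uninfected libraries, 7.66 and 6.85 in the infected ones and 6.23 and 5.86 with V46, so these stromal genes fell alongside the cholesterol genes and opposite to the interferon-stimulated genes. The number of stromal markers that fell was 1 without infected replicate 1 or V46 replicate 1 and 0 without V46 replicate 2, where the limma adjusted p was 0.082 for Col1a1 and 0.117 for Col3a1. Col3a1 did not pass without infected replicate 1 (0.0568) or V46 replicate 1 (0.0702) either. After median centring the list was called (camera, adjusted p = 0.00864). Of 8 neutrophil markers 3 fell, with 0 without infected replicate 2 or either V46 library, and of 7 lymphocyte and 5 dendritic cell markers 0 passed, also adjusted over the list alone (camera, adjusted p = 0.187, 0.689 and 0.697). Without infected replicate 1 the number of lymphocyte markers that fell was 3. Over 49997 symbols, 3 macrophage identity genes, 0 stromal and 0 neutrophil markers fell, with limma adjusted p = 0.134 for Col1a1 and 0.238 for Col3a1.

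In all, 693 genes were higher and 862 lower with V46 than in infected cells without it, and 2406 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05). After median centring the split was 1030 higher and 588 lower, since centring moved the median change of all genes from -0.07 to 0.11. Without V46 replicate 1 there were 398 higher and 420 lower genes, without V46 replicate 2 there were 340 and 398, and with the adjustment over 49997 symbols there were 235 and 288.

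The last comparison set V46-treated infected cells against uninfected cells. Gbp5 rose by 6.69 log2 units (SE 0.54, n = 2 per group, limma adjusted p = 5.78e-05) and Ifit1 by 6.69 (SE 0.39, limma adjusted p = 2.09e-05), followed by Rsad2 (6.27 ± 0.35), Cxcl2 (6.07 ± 0.64) and Ifit2 (5.95 ± 0.42). Hpgd fell (log2 fold change -5.47, SE 0.14, limma adjusted p = 6.59e-06), as did Slco2b1 (-4.42 ± 0.25), Nlrp1c-ps (-4.26 ± 0.15), Rnf150 (-3.82 ± 0.15) and Zfyve28 (-3.76 ± 0.23). All 33 measured interferon-stimulated genes rose, and 33 adjusted over the list alone, with a median of 3.68, and 19 of 20 cholesterol genes fell and 1 rose, also adjusted over the list alone, with a median of -1.37. Il1b and Il6 remained above uninfected cells with V46 (log2 fold changes 3.97, SE 0.57, and 4.12, SE 0.14). Rragd did not pass (log2 fold change 0.31, SE 0.14, limma adjusted p = 0.0724), but did after median centring (0.62, limma adjusted p = 0.00727), with an abundance of at least 5 (0.0469) and with no trend (0.0367).

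The inflammatory and stress lists stood above uninfected cells in the presence of V46. All 23 proinflammatory genes, 17 stress-response genes and 11 NRF2 targets that were measured rose, also adjusted over the list alone. Of 16 chemokine genes 13 rose and 1 fell, or 14 and 1 adjusted over the list alone, of 19 antimicrobial genes 18 rose, or 19 adjusted over the list alone, and of 15 negative feedback regulators 14 rose, also adjusted over the list alone. The cell death list had 8 of 10 genes that rose and 2 that fell, and the neutrophil list 7 of 8 that fell, also adjusted over the list alone. In all, 8 lists were called up and 2 down by camera, with adjusted p from 0.0354 for neutrophil markers to 6.76e-12 for interferon-stimulated genes, and these calls were lost with adjusted p = 0.377 with an estimated correlation, or 0.42 for neutrophil markers. The list of LXR targets (camera, adjusted p = 0.0685) was called without uninfected replicate 2 (0.0498), after median centring (0.0276) and after quantile normalization (0.00174). Under these 2 scalings the lists of alternative activation (0.0276 and 0.0197, against 0.0685) and macrophage identity (0.0459 and 0.0233, against 0.215) were called as well. With an abundance of at least 5 in 2 libraries the lists of cell death genes (0.0991) and neutrophil markers (0.0554) were not. Of the lists not called, the genes of alternative activation had 6 of 7 falling, LXR targets 8 of 10 falling and 2 rising (1 rising without uninfected replicate 2 or V46 replicate 1 and 0 without V46 replicate 2), macrophage identity genes 5 of 7 falling and stromal markers 4 of 7 falling, also adjusted over the list alone. The list of glycolysis and hypoxia genes had 4 of 6 rising and 2 falling, lymphocyte markers 5 of 7 falling and dendritic cell markers 2 of 5 rising and 2 falling, also adjusted over the list alone. Of these last, 1 rose without uninfected replicate 2 or V46 replicate 2, and 1 fell without uninfected replicate 1 or either V46 library. The 3 autophagy genes and the 2 proton pump genes rose, also adjusted over the list alone, with Sqstm1 (1.63 ± 0.12), Optn (1.61 ± 0.092) and Atp6v1h (1.40 ± 0.097) as examples.

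There were 1312 genes higher and 1924 lower in V46-treated infected cells than in uninfected cells, and 725 did not pass (limma, Benjamini-Hochberg adjusted p under 0.05). After median centring, which moved the median change of all genes from -0.23 to 0.08, the split was 1616 higher and 1210 lower. With the adjustment over 49997 symbols 1012 were higher and 1155 lower, and counts moved by over 1.5 times in the lists of LXR targets (0 rose), glycolysis (1 fell), heat shock (0 fell), antigen presentation (1 rose), dendritic cell (1 rose and 1 fell), lymphocyte (3 fell) and stromal markers (0 rose and 2 fell). By fry, 15 of the 17 tested lists were called, all but the dendritic cell (adjusted p = 0.165) and stromal markers (adjusted p = 0.0506), which again sets no list apart from the other preselected genes.

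The changes with V46 were also set against those with infection, gene by gene. Of the 1268 genes that rose with infection, 402 fell with V46, among them Il6, Cxcl3 and Sqle, and 282 rose further, among them Rsad2 and Ifit1. Independent lists of these sizes would share 275.9 and 221.8 genes. Of the 1584 genes that fell with infection, 253 rose with V46, among them Abcg1, Pparg and Rragd, and 256 fell further, among them Maf and Arg1, where independent lists would share 277.1 and 344.7. Unchanged groups simulated against the same libraries gave 0 such genes in 100 refits, which does not measure how far the shared libraries raise these numbers, as hardly any gene is called without an effect. Both comparisons use the infected libraries, with opposite sign, and part of any excess of opposite changes may come from that, since 2 libraries cannot be divided with 2 in each part.

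Across the 3961 genes, which are not independent replicates, the Pearson correlation between the 2 changes was -0.10 and the Spearman correlation -0.07. Simulated groups with no effect gave a mean of -0.50 (central interval of 1000 simulations, -0.54 to -0.46). The shared infected libraries fix that value whatever the genes do, so it is no test of the observed one. The simulations drew independent noise for each gene and made no preselection. The covariance was -0.074, against -0.013 simulated with no effect, a difference of -0.061.

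**Figure D3:**
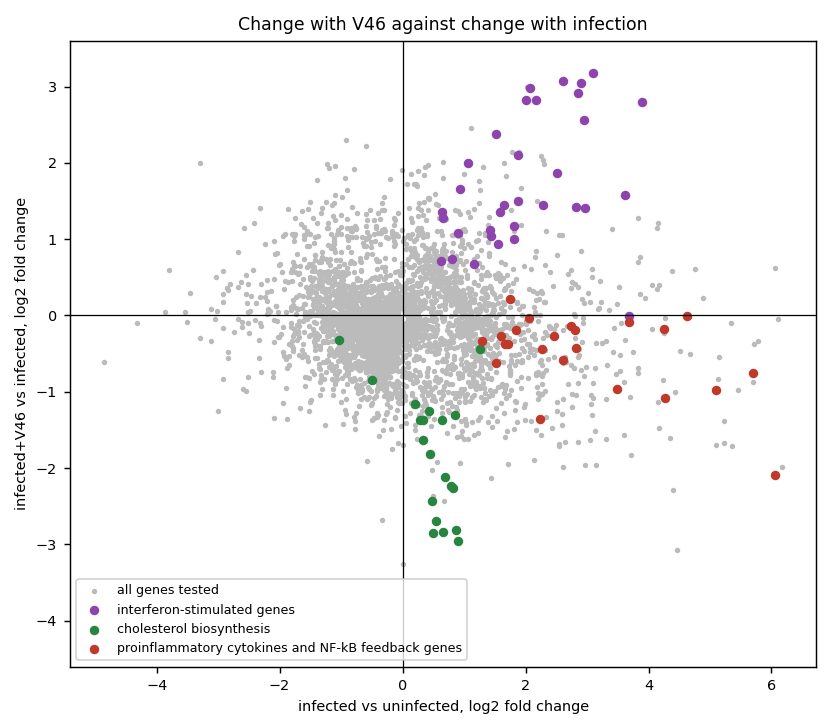
Log2 fold change with V46 in infected cells (vertical axis) against log2 fold change with infection (horizontal axis) for 3961 genes, with the members of 3 gene lists in colour. Interferon-stimulated genes lie to the upper right (medians 1.87 and 1.45), and cholesterol genes lie below 0 on the vertical axis (median -1.73).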

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

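Counts of calls depended on thresholds and single libraries, with main values given in the results. For infection, 704 genes were higher and 575 lower with a log2 fold change of at least 1, and 996 were lower after adjustment over 49997 symbols and 818 with an abundance of at least 5 in 2 libraries. For V46 in infected cells, 227 were higher and 250 lower with a log2 fold change of at least 1, 363 and 482 with an abundance fold of at least 2, and 235 and 288 after adjustment over 49997 symbols. Without 1 library at a time these counts ranged from 340 to 720 and from 398 to 912, the low values without a V46 library (398 and 420 without replicate 1, 340 and 398 without replicate 2). For V46-treated infected against uninfected cells, 797 were higher and 798 lower with a log2 fold change of at least 1, and 1155 were lower after adjustment over 49997 symbols, 920 with an abundance of at least 5 and 1210 after median centring. Leaving out 1 library gave 1145 to 1270 higher and 1353 to 1580 lower genes for infection.

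The correlation between the V46 and infection changes (-0.10, SD 0.0062 from simulation) was -0.118 with a pseudocount of 0.1, -0.118 after quantile normalization, -0.0780 with an abundance of at least 5, -0.0895 with at least 1, and -0.0509 to -0.147 without 1 library. It was -0.0325 when infected replicate 1 was set against uninfected cells and replicate 2 against V46, and -0.101 in the reverse split, and the cause was not tested. For Ifi30 the change with infection was -0.57 after quantile normalization (limma adjusted p = 0.00667) against 0.019 and no call without it, so that the sign turned and a downward call was gained.

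Of 4865 alternatives to 307 named gene results, 4642 gave the same call, 191 a weaker and 31 a stronger one, and of 801 alternatives to 51 list results, 749 the same, 44 a weaker, of which 25 came from the estimated correlation, and 8 a stronger one. Named genes were mostly chosen for large changes or a large moderated t, which favours an unchanged call. Their numbers therefore do not measure how stable the calls of all genes were. With the replicate number as a block, 1232 genes were higher and 1535 lower with infection, 626 and 763 with V46 in infected cells and 1274 and 1873 with V46 against uninfected cells. Deviations of libraries with the same number correlated at -0.27 between uninfected and infected cells. The correlations were 0.12 between uninfected and V46 and 0.11 between infected and V46 cells. As genes move together, these values cannot tell whether libraries with the same number shared an animal, culture or batch. Absolute read depth was unknown, so sampling noise of low genes was not estimated and small changes there cannot be told from it.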

Other observations

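The gene lists in this part were written after the results were seen and may have been shaped by them. Their camera values therefore describe these genes and are not independent tests. Of 8 measured genes of fatty acid synthesis and desaturation, 6 fell and 1 rose with V46 in infected cells, and 6 and 1 adjusted over the list alone, with Scd2 (-3.25 ± 0.10), Fads2 (-2.43 ± 0.17) and Elovl6 (-1.09 ± 0.18) falling and Lpin1 (0.59) rising (camera, adjusted p = 0.0104, and adjusted p = 0.498 with an estimated correlation). Without V46 replicate 1 the numbers were 5 and 0. Of 7 genes controlled by the nuclear receptor PPAR gamma and genes of fatty acid oxidation, 7 fell with infection, led by Angptl4 (-2.06) and Pparg (-1.86) (camera, adjusted p = 0.0125, and adjusted p = 0.303 with an estimated correlation). With V46, 3 of them rose, namely Pparg, Fabp4 and Plin2, also adjusted over the list alone (camera, adjusted p = 0.0513). Of 6 genes of oxysterol formation and sterol storage, 2 fell and 1 rose with V46, or 3 and 2 adjusted over the list alone, with Soat2 (-0.72) and Nceh1 (0.95) as examples (camera, adjusted p = 0.761). Without either V46 library 1 of them fell, and without infected replicate 2, 3 fell and 2 rose. With the adjustment over 49997 symbols the 4 comparisons of this paragraph gave, in order, 4 falling and 0 rising, 7 falling, 3 rising, and 0 falling and 1 rising genes.

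The lists of this paragraph, too, were written after the results, and their camera values only describe them. Of 18 measured receptors for purines, prostaglandins and lipid mediators, of 20 in the list, 7 fell and 1 rose with V46, or 8 and 1 adjusted over the list alone. Adora2b (-1.96 ± 0.17), S1pr1 (-1.48 ± 0.13), Ptger4 (-1.44 ± 0.13) and P2ry6 (-1.39 ± 0.094) fell, and the list moved down (camera, adjusted p = 0.0329, and adjusted p = 0.498 with an estimated correlation). Without any 1 of the infected or V46 libraries 0 of them rose, and without uninfected replicate 1, 2 rose. Of 5 genes that start or restrain the type I interferon response, Tlr3 (1.47) and Trex1 (1.11) rose and Ikbke (-0.68) fell. Tlr3 encodes a receptor for double-stranded RNA. Altogether 4 of the 5 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.0522). Without either V46 library 1 of them rose, and without V46 replicate 2, 0 fell. Of 11 extracellular matrix genes, 7 fell, also adjusted over the list alone, such as Col6a2 (-1.34) and Fbn1 (-1.15) (camera, adjusted p = 0.0151, and adjusted p = 0.507 with an estimated correlation). The number was 1 without infected replicate 1 or V46 replicate 1 and 0 without V46 replicate 2. With the adjustment over 49997 symbols 0 of the matrix genes, 6 receptors and 0 genes of the interferon list fell. Under it 0 receptors and 1 gene of the interferon list rose.

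The tests in this part were chosen after the result was seen. Genes that infection raised were higher in uninfected replicate 2 than in replicate 1, here weighed on the 76 abundant genes at least 16-fold higher in infected cells than in uninfected replicate 1. That choice favours low values in replicate 1, but 43 genes chosen on replicate 2 instead had a median difference of 0.63. A scaling difference is argued against by the 3885 genes outside the 76, which had a median difference of 0.032, against 0.78 in the 76. Admixture of infected material might give this and was left open: it needs a share of the infected level alike across genes, and the 90th percentile of that share was 8.23 times its 10th (bootstrap interval 4.84 to 12.3), but 4.80 times (2.74 to 8.15) in the 31 most abundant genes. No biological explanation was tested.

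The tests in this part were chosen after the result was seen. Interferon-stimulated genes were higher with V46, and infected replicate 2 was the lower of the infected libraries. Both V46 libraries lay above both infected libraries in 32 of 33 genes, which a low infected replicate 2 alone would not give. An effect of V46 and the spread between infected libraries still cannot be told apart here. The V46 libraries lay above infected replicate 1 by a median of 1.04, while the infected libraries differed by 1.06, and the genes of this list move almost as one. The 3 collagen genes, like this list, were higher in infected replicate 1 than in replicate 2, by a median of 0.79, but lower with V46, by -1.28, and what part cell mixture had was left open. Further infected cultures with and without V46 would test it.

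The tests in this part were chosen after the result was seen. Cholesterol synthesis genes were lower with V46, as were collagen genes, but 45% of the list fell by more than every collagen gene, by over 2 SE (9 of 20), so stromal loss alone may not account for those 9, and the test leaves it open for the other genes. Scaling is argued against by a median of -1.54 after median centring, the smaller of 2 scalings. More transcript of Ch25h, whose product represses the pathway, is argued against by its change of -1.05 (SE 0.25, limma adjusted p = 0.017). Adjusted over the RefSeq symbols the fall did not pass (limma adjusted p = 0.215), so the values speak only against a rise with V46. Ch25h in V46-treated cells stayed above uninfected cells (log2 fold change 1.18, SE 0.25), and the level of its product was not measured. A hypothesis is that V46 adds to cell sterol or lowers SREBP2 activity, which sterol measurements and processed SREBP2 protein would test.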
